A study of Sus scrofa with 23 samples.

How the data were processed

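Gene expression was measured with a porcine Affymetrix array in 23 samples of offspring of German Landrace gilts on a gestational low-protein diet, at 94 dpc (5 samples) and at 1, 28 and 188 dpn (6 samples each). Per the labels' protocols, total RNA was extracted with TRI Reagent, treated with DNase, cleaned on RNeasy columns and turned into biotin-labelled cRNA from 0.5 ug. The labels give the stage of every sample. Replicate numbers follow accession order and only name a sample. All samples were labelled liver and the series title names muscle.

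The deposited values are intensities: 1 linear signal per probe set and array, for 24123 probe sets. GCOS 1.1.1 is named in the submitters' processing notes, without its role. The summarisation algorithm and the background correction are not given in the sources used here, nor are detection calls, so no probe set could be said to be absent. The 2% trimmed mean over all probe sets lay at 500.1 to 500.2 on each of the 23 arrays, from which the values were taken as scaled to one target. Such scaling fixes the mean of bright and dim probe sets together, so that a shift of many transcripts on 1 array moves all of its others. No pair of arrays held identical values, and 0 columns were without a sample.

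A table of probe annotations paired 10069 probe sets with 1 gene symbol and 198 with several, while 13732 had none. Entrez identifiers of 9961 were found in the RefSeq gene table, and 0 symbols needed updating. Genes were named only from probe sets with 1 symbol. Each of the 6765 genes was represented by its probe set with the highest mean over all samples, and the other probe sets of a gene were run as an alternative. Of 2261 genes with several probe sets, 44, 20, 4 and 66 had probe sets called in both directions in the 4 comparisons, in the order of the results.

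The 124 Affymetrix control probe sets were left out of the tests, which left 23999. Values were taken as log2(signal + 16) without further normalization, since the table was already scaled. A linear model with 1 mean per stage was fitted to all 23 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. Comparisons were 1 dpn with 94 dpc, 28 dpn with 1 dpn, 188 dpn with 28 dpn and 188 dpn with 94 dpc. Tests were two-sided, with Benjamini-Hochberg adjustment over all probe sets of a comparison, and a probe set was called at an adjusted p under 0.05. The unadjusted p was under 0.05 for 8696, 6981, 6174 and 10584 probe sets. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and tables were read with pandas 2.3.3.

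Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, and again with the correlation estimated from the data, with Benjamini-Hochberg adjustment over the 34 lists of at least 3 measured genes. A list of sex-linked genes had 2 and was not tested. Counts adjusted over the list alone apply the adjustment to the members of that list. The genes named were, per comparison, the 10 largest rises and the 10 largest falls among called genes whose samples did not overlap between the stages and whose mean in the higher stage lay above the median of all probe sets (7.15 on the log2 scale). Added to these were up to 4 called members of each described list with the largest change. The rule also provided for any member of a list with at most 12 measured genes, but no genes were added by that clause. AFP, ALB, IGF1, IGF2, CPS1, PCK1 and CYP7A1 were named in every comparison, and G6PC belonged to the same rule but was not analysed here. The rule's remaining genes are not reported here. The comparisons, the lists, this rule and all alternatives except 3 were fixed before the data were examined.

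The alternatives were quantile normalization, centring each array on its median, leaving out the dimmer probe sets, pseudocounts of 1 and 64, fitting only the stages compared, eBayes with trend and robust options, array weights, leaving out each sample in turn, the mean of all probe sets of a gene, camera on ranks, and the estimated correlation. The added 3, chosen after seeing the data, left out the 1 dpn samples of low GAPDH ratio, used the GAPDH ratio as a covariate and used the Dap ratio as a covariate.

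The fit was tested on simulated data of 23999 probe sets with log2 changes of 1 and 2 planted in 100 probe sets each. For 1 dpn against 94 dpc, 26 and 88 were recovered with 5 false calls. For 28 dpn against 1 dpn these were 32, 81 and 8, for 188 dpn against 28 dpn 37, 94 and 5, and for 188 dpn against 94 dpc 29, 92 and 4. A shift of 0.5 planted in the 34 cell cycle genes among 6765 was found in the 4 comparisons at adjusted p = 5e-12, 4.7e-15, 1.5e-17 and 1e-09, with 0, 0, 0 and 1 of the other 33 lists called. The simulated noise was independent between probe sets, whereas the estimated correlation in the data reached 0.482 (interferon-stimulated list). False calls of lists with correlated genes were therefore not measured. In these simulations, 2-fold changes of single probe sets were thus missed more often than found. Far fewer probe sets were changed there than were called in the data, which makes the adjusted threshold stricter. The share missed in the data was therefore not measured.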

Results

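The data were signals of 23 porcine Affymetrix expression arrays, each hybridised with labelled cRNA from the total RNA of 1 animal's tissue sample. The animals were offspring of German Landrace gilts fed a low-protein diet during gestation. They were sampled at 94 days post conception (dpc, 5 samples, before birth) and at 1, 28 and 188 days post natum (dpn, 6 samples each), the usual reading of the labels' abbreviations. Every sample came from the low-protein group, so the arrays compare ages and hold no test of diet. Offspring of 3 gilts were collected per stage and the labels do not give the dam, so some animals of a stage shared one. The p-values treat the animals as independent and may for that reason be too small. The fit also took 1 spread per probe set for all stages, although the samples of 1 dpn were least alike. Their median pairwise correlation was 0.905, against 0.931 to 0.951 at the other stages. Errors of the comparisons with 1 dpn may therefore be understated, and those of the other comparisons overstated. The median signal of the arrays lay between 120.8 and 168.8, and the number of arrays limits the precision. Signals are given as mean ± SD, with n = 5 at 94 dpc and n = 6 at each other stage. Folds are differences of stage means on the scale of log2(signal + 16), turned back to ratios. They therefore need not equal the ratio of the mean signals beside them, and the added 16 draws the folds of dim transcripts toward 1.

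The tissue named in the records was in conflict: each sample is labelled liver, while the title of the series names muscle. Transcripts of skeletal muscle were among the brightest of every array. Creatine kinase of muscle (CKM) had a mean signal of 42900 ± 3300 (SD, n = 5) at 94 dpc and 86700 ± 10700 (n = 6) at 188 dpn, and the myosin light chain MYL1 had 49900 ± 5060 and 94800 ± 11500, both genes picked after their values were seen. Albumin (ALB), the main secreted protein of hepatocytes, had 385 ± 435 at 94 dpc, 1230 ± 1080 at 1 dpn, 1170 ± 2560 at 28 dpn and 3640 ± 2880 at 188 dpn. The 26 measured skeletal muscle genes had a median percentile of 99 to 99.8 among all probe sets of a sample. For 39 plasma protein genes it was 23.5 to 80.6, and for 32 genes of xenobiotic metabolism 32.9 to 71.9. The samples are therefore called samples labelled liver throughout, and no result below is assigned to a tissue. Percentiles compare lists within an array, where different probe sets need not be equally sensitive.

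**Figure D1:**
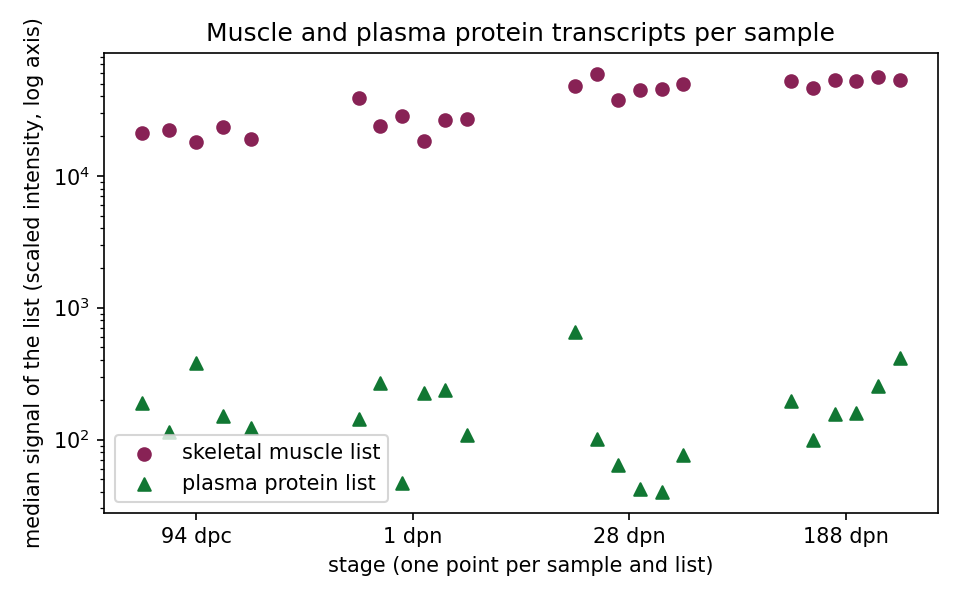
Median signal of the skeletal muscle list and of the plasma protein list (scaled intensity, log axis) in each of the 23 samples, by stage, with 1 point per sample and list. In every sample the muscle list lies above the plasma protein list.

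At 1 dpn, 3 of the 6 samples (replicates 2, 4 and 5) had a GAPDH 5' to 3' signal ratio of 0.0868 to 0.148, against 1.09 to 1.29 in the other 20 samples. The GAPDH control probe sets report how far labelled copies reach from the 3' end toward the 5' end of a transcript. Comparisons with 1 dpn are given below with all samples, and the counts without these 3 samples, a setting chosen after seeing the data, stand beside them. The bacterial spike-in Dap had low ratios in all 28 dpn samples (at most 0.0977) and high ones in all 188 dpn samples (at least 0.264), so that this ratio separated 28 dpn from 188 dpn completely. The bioD control signal was 9677 to 14140 at 94 dpc, 24570 to 41780 at 1 dpn and 19020 to 23230 at 188 dpn. The actin 5' to 3' ratio was 0.82 to 1.1 at 94 dpc and 0.817 to 1.21 at 1 dpn. It was 1.32 to 1.61 at 28 dpn and 1.29 to 1.42 at 188 dpn. Each comparison was thus separated by some control measure, and age cannot be told apart from what it reflects. Neither bioD nor actin was used as a covariate.

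**Figure D2:**
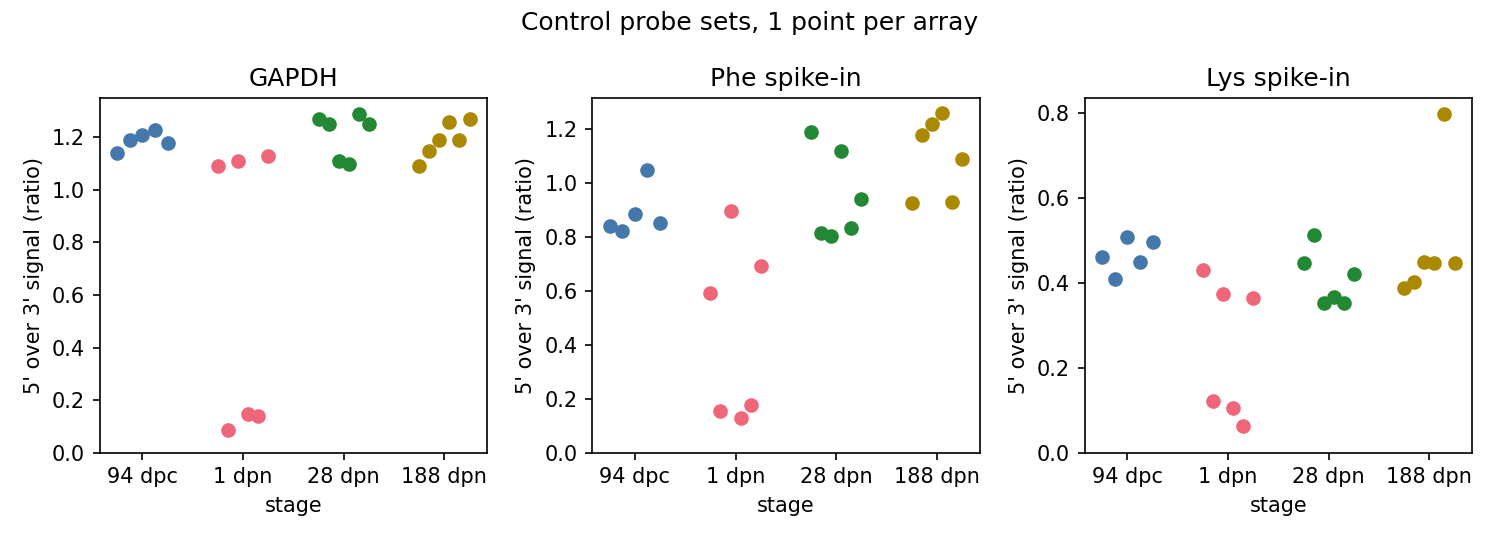
Signal of the 5' probe set over that of the 3' probe set for GAPDH and for the spike-in transcripts Phe and Lys (ratio, linear axes from 0), with 1 point per array and the stages on the horizontal axis. The 3 arrays of low GAPDH ratio at 1 dpn are also lowest for Phe and Lys.

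The first comparison asked which transcripts differed between late gestation and the day after birth. As lists, genes of fatty acid oxidation and of the respiratory chain shifted higher at 1 dpn than at 94 dpc, and genes of the cell cycle and of matrix-forming cells shifted lower, with members in each that did not pass. With an estimated correlation, fatty acid oxidation kept its call (adjusted p = 0.039), and the respiratory chain (adjusted p = 0.14), cell cycle (adjusted p = 0.069) and matrix lists (adjusted p = 0.24) did not. PDK4, a kinase that limits the use of pyruvate in mitochondria, rose 25.7-fold (signal 11700 ± 6420 against 427 ± 166, adjusted p = 6.1e-08). CKMT2, the mitochondrial creatine kinase of striated muscle, rose 19.3-fold (signal 33300 ± 7950 against 1730 ± 468, adjusted p = 7.8e-12). Cardiac troponin T (TNNT2), which developing muscle also makes, fell 63.1-fold (signal 53 ± 64.1 against 3230 ± 711, adjusted p = 2.1e-07), and the growth factor midkine (MDK) fell 54.5-fold (signal 74.5 ± 90.4 against 3330 ± 502, adjusted p = 4e-08).

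In all, 1939 of 23999 probe sets were higher and 4284 lower at 1 dpn, together 25.9% of those tested, and 1081 and 2644 of them differed at least 2-fold. By gene, 925 were higher and 1313 lower of 6765. The other genes with the largest rises were LOC100153598, TP53INP2, AGT (angiotensinogen), CLIP4, TRNP1, FKBP5, ANKRD1 and HSPB7, at 10.6-fold to 26.1-fold. FKBP5 encodes a co-chaperone of the glucocorticoid receptor, and ANKRD1 and HSPB7 are made in striated muscle. The other large falls were those of MYL4, POSTN, VCAN, UBE2C, LXN, SPP1, CCNB1 and CDO1, at 10.5-fold to 24-fold. MYL4 is the myosin light chain of embryonic and atrial muscle. POSTN and VCAN encode periostin and versican of the extracellular matrix, and UBE2C and CCNB1 act in mitosis.

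Gene groups are described by lists fixed in advance, with log2 changes ± SE for the members that changed most. Among genes of the respiratory chain and ATP synthase, 52 of 60 rose and 8 did not pass (53 rose adjusted over the list alone), with adjusted p = 3.8e-24 for the list and adjusted p = 0.14 with an estimated correlation. The largest rises were those of ATP5I (2.75 ± 0.56), NDUFC1 (1.98 ± 0.19), UQCRB (1.87 ± 0.16) and NDUFA9 (1.70 ± 0.17). Among genes of fatty acid oxidation and ketone body formation, 18 of 28 rose and 10 did not pass (19 rose adjusted over the list alone), with adjusted p = 1.3e-10 for the list and adjusted p = 0.039 with an estimated correlation. PDK4 was followed by ACADVL, the mitochondrial dehydrogenase for very long acyl chains (2.81 ± 0.22), ANGPTL4, an inhibitor of lipoprotein lipase (2.54 ± 0.34), and HADHB (2.24 ± 0.18). In the antioxidant and metal-binding list, 10 of 26 rose and 16 did not pass (11 rose adjusted over the list alone), with adjusted p = 0.0029 for the list and adjusted p = 0.24 with an estimated correlation. The members that rose most were GPX2 (2.30 ± 0.58), SOD2 (2.20 ± 0.23), GCLM (2.10 ± 0.34) and GPX1 (1.68 ± 0.24). Of gluconeogenesis and glycogen genes, 5 of 14 rose and 9 did not pass (5 rose adjusted over the list alone), with adjusted p = 0.031 for the list and adjusted p = 0.24 with an estimated correlation. They included PCK2 (1.97 ± 0.64), UGP2 (1.21 ± 0.28), PPP1R3B (1.1 ± 0.32) and GYG1 (1.09 ± 0.24).

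In the cell cycle list, 27 of 34 fell and 7 did not pass (29 fell adjusted over the list alone), with adjusted p = 7.6e-11 for the list and adjusted p = 0.069 with an estimated correlation. The mitotic genes UBE2C (-3.73 ± 0.52), CCNB1 (-3.43 ± 0.32), MELK (-2.79 ± 0.27) and CKS2 (-2.70 ± 0.26) fell most. Among markers of matrix-forming cells, 17 of 27 fell and 10 did not pass (19 fell adjusted over the list alone), with adjusted p = 7e-05 for the list and adjusted p = 0.24 with an estimated correlation. These were led by POSTN (-4.32 ± 0.36), COL1A2 (-2.38 ± 0.35), THY1 (-2.30 ± 0.44) and COL5A2 (-2.19 ± 0.40). Of endothelial markers, 9 of 15 fell and 6 did not pass (9 fell adjusted over the list alone), with adjusted p = 0.0033 for the list and adjusted p = 0.14 with an estimated correlation, the largest falls being those of TIE1 (-3.06 ± 0.31), RAMP2 (-1.99 ± 0.24), CLDN5 (-1.85 ± 0.34) and CDH5 (-1.66 ± 0.24). In the skeletal muscle list, 8 of 26 rose, 2 fell and 16 did not pass (12 rose and 2 fell adjusted over the list alone), with adjusted p = 0.0033 for the list and adjusted p = 0.49 with an estimated correlation. The calcium pump of fast muscle, ATP2A1, changed most (3.28 ± 0.17), followed by XIRP2 (2.01 ± 0.24), MYL3 (1.90 ± 0.25) and PYGM (1.68 ± 0.26). Among ribosomal protein genes, 9 of 61 rose, 1 fell and 51 did not pass (8 rose and 1 fell adjusted over the list alone), with adjusted p = 0.0081 for the list and adjusted p = 0.79 with an estimated correlation, with RPS27L (1.07 ± 0.25), RPLP2 (0.68 ± 0.25) and RPL27 (0.63 ± 0.16) higher and RPS24 (-0.70 ± 0.23) lower.

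Of the genes named in every comparison, IGF1 fell by 1.78 ± 0.36 on the log2 scale (adjusted p = 0.00072). The log2 changes of AFP (-1.28 ± 0.58, adjusted p = 0.11), ALB (1.32 ± 0.99, adjusted p = 0.36), IGF2 (-0.87 ± 0.37, adjusted p = 0.088), CPS1 (0.85 ± 0.49, adjusted p = 0.22), PCK1 (0.74 ± 0.63, adjusted p = 0.43) and CYP7A1 (0.15 ± 0.27, adjusted p = 0.75) did not pass the test. IGF2 passed without 1 dpn replicate 6 (adjusted p = 0.0087), and 5 of its 12 other probe sets were lower at 1 dpn (log2 changes of -1.43 to -3.15, adjusted p from 2e-05 to 0.0095), while none passed as higher.

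Single samples carried some of these calls. PCK2 lost its call without 94 dpc replicate 2 or 1 dpn replicate 5 (adjusted p from 0.06 to 0.064), RPS24 without 94 dpc replicate 4 or 1 dpn replicate 4 or 5 (adjusted p from 0.055 to 0.063) and RPLP2 without 94 dpc replicate 2, 3, 4 or 5 or 1 dpn replicate 1, 3 or 6 (adjusted p from 0.061 to 0.11). The gluconeogenesis and glycogen list did so without 94 dpc replicate 4 or 1 dpn replicate 1 or 4 (adjusted p from 0.05 to 0.073) and the ribosomal protein list without 1 dpn replicate 1 (adjusted p = 0.12), while glycolysis (adjusted p = 0.067) passed without 1 dpn replicate 2 (adjusted p = 0.0083). Without the 3 samples of low GAPDH ratio, 1875 probe sets were higher and 4132 lower, of which 1324 and 3187 were among those called with all samples. Fold changes that differed by more than 1.5 times in that setting included, as log2 changes, 3.05 for FKBP5, -5.01 for TNNT2, -4.62 for MDK, -1.38 for RAMP2, -1.04 for CLDN5, 0.47 for RPS27L (adjusted p = 0.059) and -2.37 for AFP (adjusted p = 0.0076). ALB, not called, turned from 1.32 to -0.14 (adjusted p = 0.95), and CPS1 moved from 0.85 to 0.23 (adjusted p = 0.82). PCK2 (adjusted p = 0.2), RPS24 (adjusted p = 0.51) and RPL27 (adjusted p = 0.053) no longer passed. The glycolysis list did (adjusted p = 0.0027). Other settings changed further calls, with the adjusted p in parentheses. With a pseudocount of 1, PCK2 (0.073) did not pass. With the GAPDH covariate, PCK2 (0.19), RPS27L (0.1), RPS24 (0.56) and RPL27 (0.054) did not pass, and AFP (0.0073), the glycolysis list (0.0037) and the interferon-stimulated list (0.05) did. With the Dap covariate, PCK2 (0.058) and RPS24 (0.067) did not pass, and the glycolysis list (0.033) did. Fitted on the stages compared alone, PPP1R3B (0.051), RPS24 (0.1) and RPLP2 (0.13) did not pass, and the acute phase and complement list (0.034) did. After centring, RPS24 (0.16) and the gluconeogenesis and glycogen list (0.061) did not pass. After quantile normalization, RPLP2 (0.47), RPL27 (0.15), the gluconeogenesis and glycogen list (0.066) and the antioxidant list (0.085) did not pass, and IGF2 (0.013) did. Without the dimmer probe sets, the gluconeogenesis and glycogen list (0.069) did not pass, and IGF2 (0.049) did. Under array weights, the glycolysis list (0.041) passed. With the mean of all probe sets per gene, the glycolysis list (0.03) and the acute phase and complement list (0.011) passed. By camera on ranks, the glycolysis list (0.045) and the acute phase and complement list (0.045) passed.

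The direction of the calls depended on the scaling: 31.2% of called probe sets were higher at 1 dpn as deposited, 47.3% after quantile normalization and 59.4% after centring each array on its median. The median log2 change of all probe sets was -0.108, 0.038 and 0.165 under these settings, and small changes are relative to that shift. After quantile normalization the skeletal muscle list no longer rose (adjusted p = 0.94, with its direction turned) and the ribosomal protein list fell (adjusted p = 0.00066). Of 34 other probe sets of called genes, 15 passed in the same direction. Log2 changes of the same sign that did not pass were those of PCK2 (0.81 and 1.06), UGP2 (0.60), ANGPTL4 (1.25), HADHB (0.75), COL1A2 (-1.19), PYGM (0.72 and 0.50), GCLM (0.22), ATP5I (0.09), RPL27 (0.39 and 0.60) and IGF1 (-0.85). The opposite sign was found for LOC100153598 (-0.16), VCAN (0.40 and 0.05), UBE2C (0.26), COL5A2 (0.45) and IGF1 (0.34).

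The second comparison covered the first 4 weeks of life, from 1 to 28 dpn. As lists, interferon-stimulated, antigen presentation and skeletal muscle genes shifted higher at 28 dpn and the fetal liver list shifted lower. With an estimated correlation none of these kept its call (adjusted p = 0.46, 0.46, 0.46 and 0.44), and of the skeletal muscle genes 13 of 26 rose. MYH2, the fast IIa myosin heavy chain, rose 12-fold (signal 76900 ± 17100 against 6680 ± 2930, adjusted p = 3.7e-08). GAMT, the last enzyme of creatine synthesis, rose 24.3-fold (signal 5230 ± 1250 against 392 ± 517, adjusted p = 5.2e-06), and GPD1, a glycerol phosphate dehydrogenase, rose 21.5-fold (signal 19600 ± 1870 against 2220 ± 3300, adjusted p = 8.1e-05). The paternally expressed gene PEG10 fell 8.93-fold (signal 445 ± 182 against 4230 ± 2060, adjusted p = 1e-06), while its other 2 probe sets had log2 changes of -0.34 (adjusted p = 0.68) and 1.89 (adjusted p = 0.00025).

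A total of 2435 probe sets were higher and 1686 lower at 28 dpn, 17.2% of 23999, and 1359 and 772 of them differed at least 2-fold. By gene, 910 were higher and 719 lower. The other large rises were those of MSS51, C4BPA, MDK, CCL5, EGF, ALDH2 and STBD1, at 10.1-fold to 17.7-fold. C4BPA binds complement factor C4b, CCL5 is a chemokine of T cells and STBD1 binds glycogen. The other large falls were those of RNF207, MYO5B, PNMT, ATP5I, LOC396711, PLAGL1, FOSL2, CDKN3 and SLC25A33, at 5.09-fold to 9.79-fold. PLAGL1 is an imprinted zinc finger gene, and PNMT makes adrenaline from noradrenaline.

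Among interferon-stimulated genes, 17 of 21 rose and 4 did not pass (17 rose adjusted over the list alone), with adjusted p = 4.3e-08 for the list and adjusted p = 0.46 with an estimated correlation. The largest rises were those of GBP1 (3.39 ± 0.54), RSAD2 (3.27 ± 0.72), OAS1 (2.81 ± 0.72) and UBD (2.78 ± 0.41). In the antigen presentation list, 16 of 22 rose, 1 fell and 5 did not pass (16 rose and 1 fell adjusted over the list alone), with adjusted p = 4.2e-07 for the list and adjusted p = 0.46 with an estimated correlation. The swine leukocyte antigen genes SLA-DRA (3.06 ± 0.44), SLA-DQA1 (2.68 ± 0.40), SLA-2 (2.61 ± 0.47) and SLA-DQB1 (2.50 ± 0.40) led it. Of macrophage markers, 8 of 17 rose and 9 did not pass (9 rose adjusted over the list alone), with adjusted p = 0.0039 for the list and adjusted p = 0.46 with an estimated correlation, with LAPTM5 (2.57 ± 0.31), C1QC (2.40 ± 0.39), CTSS (1.92 ± 0.22) and AIF1 (1.80 ± 0.31) at the top. The macrophage list shares 2 of its 17 genes with other lists. Among cell cycle genes, 14 of 34 rose and 20 did not pass (16 rose adjusted over the list alone), with adjusted p = 0.00012 for the list and adjusted p = 0.46 with an estimated correlation. The list was led by CCNB1 (2.45 ± 0.31), UBE2C (2.43 ± 0.50), RACGAP1 (1.79 ± 0.29) and MELK (1.69 ± 0.26).

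Among skeletal muscle genes, 13 of 26 rose, 2 fell and 11 did not pass (14 rose and 2 fell adjusted over the list alone), with adjusted p = 0.00044 for the list and adjusted p = 0.46 with an estimated correlation. MYH2 was followed by RYR1, the calcium release channel (1.77 ± 0.19), and MYBPC1 (1.45 ± 0.35), while MYF5, a regulator of early myogenesis, fell (-0.97 ± 0.31). In amino acid breakdown, 8 of 28 rose and 20 did not pass (8 rose adjusted over the list alone), with adjusted p = 0.032 for the list and adjusted p = 0.46 with an estimated correlation. The members that rose most were KMO (1.71 ± 0.36), BCAT2 (1.61 ± 0.35), BCKDHB (1.59 ± 0.27) and HIBCH (1.49 ± 0.28). Of the fetal liver list, 4 of 7 fell and 3 did not pass (5 fell adjusted over the list alone), with adjusted p = 0.0044 for the list and adjusted p = 0.44 with an estimated correlation. Its falls were those of PEG10 (-3.16 ± 0.34), PLAGL1 (-2.68 ± 0.29), AFP (-1.84 ± 0.56) and IGF2 (-1.1 ± 0.35), of which PEG10, PLAGL1 and IGF2 are imprinted genes active in many fetal tissues. In the respiratory chain list, 2 of 60 rose, 12 fell and 46 did not pass (2 rose and 17 fell adjusted over the list alone), with adjusted p = 0.0037 for the list and adjusted p = 0.69 with an estimated correlation, led by ATP5I (-2.82 ± 0.53), COX7A2 (-1.57 ± 0.16), NDUFC2 (-0.93 ± 0.18) and NDUFA2 (-0.85 ± 0.20). Of ribosomal protein genes, 14 of 61 fell and 47 did not pass (21 fell adjusted over the list alone), with adjusted p = 0.00013 for the list and adjusted p = 0.62 with an estimated correlation. They included RPL3 (-1.36 ± 0.14), RPLP2 (-1.22 ± 0.23), RPL31 (-0.70 ± 0.16) and RPS25 (-0.68 ± 0.15).

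IGF1 rose by 1.56 ± 0.35 on the log2 scale (adjusted p = 0.0028), and its change had the opposite sign between 94 dpc and 1 dpn. The changes of ALB (-1.54 ± 0.94, adjusted p = 0.3), CPS1 (-1.30 ± 0.47, adjusted p = 0.059), PCK1 (-0.66 ± 0.60, adjusted p = 0.52) and CYP7A1 (-0.20 ± 0.26, adjusted p = 0.68) did not pass. ALB passed without 28 dpn replicate 1 (adjusted p = 0.03) and CPS1 without 1 dpn replicate 1 or 3 or 28 dpn replicate 1 (adjusted p from 0.012 to 0.045). Without the 3 samples of low GAPDH ratio their log2 changes were -0.08 (adjusted p = 0.98) and -0.69 (adjusted p = 0.49).

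Calls that single samples carried were those of AFP, lost without 1 dpn replicate 2, 4 or 5 or 28 dpn replicate 3 or 6 (adjusted p from 0.052 to 0.065), of IGF2, lost without 1 dpn replicate 3 or 6 or 28 dpn replicate 1, 2, 5 or 6 (adjusted p from 0.058 to 0.087), and of MYF5, lost without 1 dpn replicate 3, 4 or 5 or 28 dpn replicate 1, 4 or 5 (adjusted p from 0.054 to 0.074). The respiratory chain list lost its call without 1 dpn replicate 1 (adjusted p = 0.13) and amino acid breakdown without 1 dpn replicate 3 or 28 dpn replicate 1 (adjusted p = 0.055). Lists that passed after leaving out 1 sample were plasma proteins, which then fell without 1 dpn replicate 3 or 28 dpn replicate 1 (adjusted p from 0.00089 to 0.017), and glycolysis without 1 dpn replicate 1 (adjusted p = 0.035). The same held for granulocyte markers without 1 dpn replicate 2, 3, 4 or 5 or 28 dpn replicate 3 or 5 (adjusted p from 0.026 to 0.049), endothelial markers without 28 dpn replicate 3 (adjusted p = 0.048) and immediate early genes without 1 dpn replicate 4 or 6 or 28 dpn replicate 3 or 4 (adjusted p from 0.02 to 0.044). The log2 change of GAMT was 3.98 without 1 dpn replicate 2, that of GPD1 5.08 without 1 dpn replicate 1 and 3.55 without 1 dpn replicate 2, and that of RSAD2 4.00 without 1 dpn replicate 6.

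Without the 3 samples of low GAPDH ratio at 1 dpn, 1990 probe sets were higher and 1227 lower, of which 1463 and 781 were among the 2435 and 1686 called with all samples. RSAD2 (2.20, adjusted p = 0.095), OAS1 (1.21, adjusted p = 0.31), MYBPC1 (0.48, adjusted p = 0.18), BCAT2 (0.77, adjusted p = 0.068), AFP (-0.74, adjusted p = 0.48) and MYF5 (-1.02, adjusted p = 0.081) then did not pass. GAMT (3.26), GPD1 (3.20), MDK (2.74), STBD1 (2.75), SLA-DRA (1.96), SLA-DQA1 (1.79), SLA-2 (1.35), SLA-DQB1 (1.61) and C1QC (1.46) kept their calls, with fold changes smaller by more than 1.5 times. Fatty acid oxidation (adjusted p = 0.022) and granulocyte markers (adjusted p = 0.018) passed in that setting, and amino acid breakdown did not (adjusted p = 0.08). Of called probe sets, 59.1% were higher at 28 dpn as deposited, 53.3% after quantile normalization and 49.2% after centring (1974 higher and 2041 lower). With the 1 and 28 dpn samples fitted alone, 1487 probe sets were higher and 966 lower. With the GAPDH ratio as a covariate, 1795 were higher and 1112 lower. Further calls changed as follows, with the adjusted p in parentheses. With a pseudocount of 64, CPS1 (0.048), the granulocyte list (0.045) and the immediate early list (0.045) passed. With the GAPDH covariate, AFP (0.48), BCAT2 (0.14), RSAD2 (0.11), OAS1 (0.36), MYBPC1 (0.3), MYF5 (0.078), the amino acid breakdown list (0.067) and the skeletal muscle list (0.069) did not pass, and the fatty acid oxidation list (0.018) and the granulocyte list (0.018) did. With the Dap covariate, IGF2 (0.081) and MYF5 (0.067) did not pass, and CPS1 (0.046) and the endothelial list (0.027) did. Fitted on the stages compared alone, AFP (0.062) and IGF2 (0.12) did not pass, and the immediate early list (0.029) did. After centring, CPS1 (0.045) passed. Without the dimmer probe sets, the amino acid breakdown list (0.057) did not pass, and the gluconeogenesis and glycogen list (0.039) did. Under array weights, IGF2 (0.069) did not pass. With the mean of all probe sets per gene, the immediate early list (0.019) passed. By camera on ranks, the plasma protein list (0.049), the granulocyte list (0.034) and the immediate early list (0.037) passed. Under the trend and robust options, CPS1 (0.039) passed. Of 32 other probe sets of called genes, 7 passed in the same direction. Log2 changes of the same sign that did not pass were those of PEG10 (-0.34), LOC396711 (-1.19), PLAGL1 (-0.53), SLC25A33 (-0.70), IGF2 (-0.09, -0.37, -0.11, -0.21, -0.28, -0.57, -0.07, -1.41 and -0.85), UBE2C (0.07), LAPTM5 (0.41), GBP1 (1.12), RPS25 (-0.25) and IGF1 (0.80). The opposite sign was found for PEG10 (1.89), ATP5I (0.46), IGF2 (1.13 and 1.45), CTSS (-0.16), RPS25 (0.45) and IGF1 (-0.29). Of the latter, PEG10 (adjusted p = 0.00025) and both IGF2 probe sets (adjusted p = 0.035 and 0.023) passed as rises, so that of the 12 other IGF2 probe sets 1 passed as a fall and 2 as rises.

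**Figure D3:**
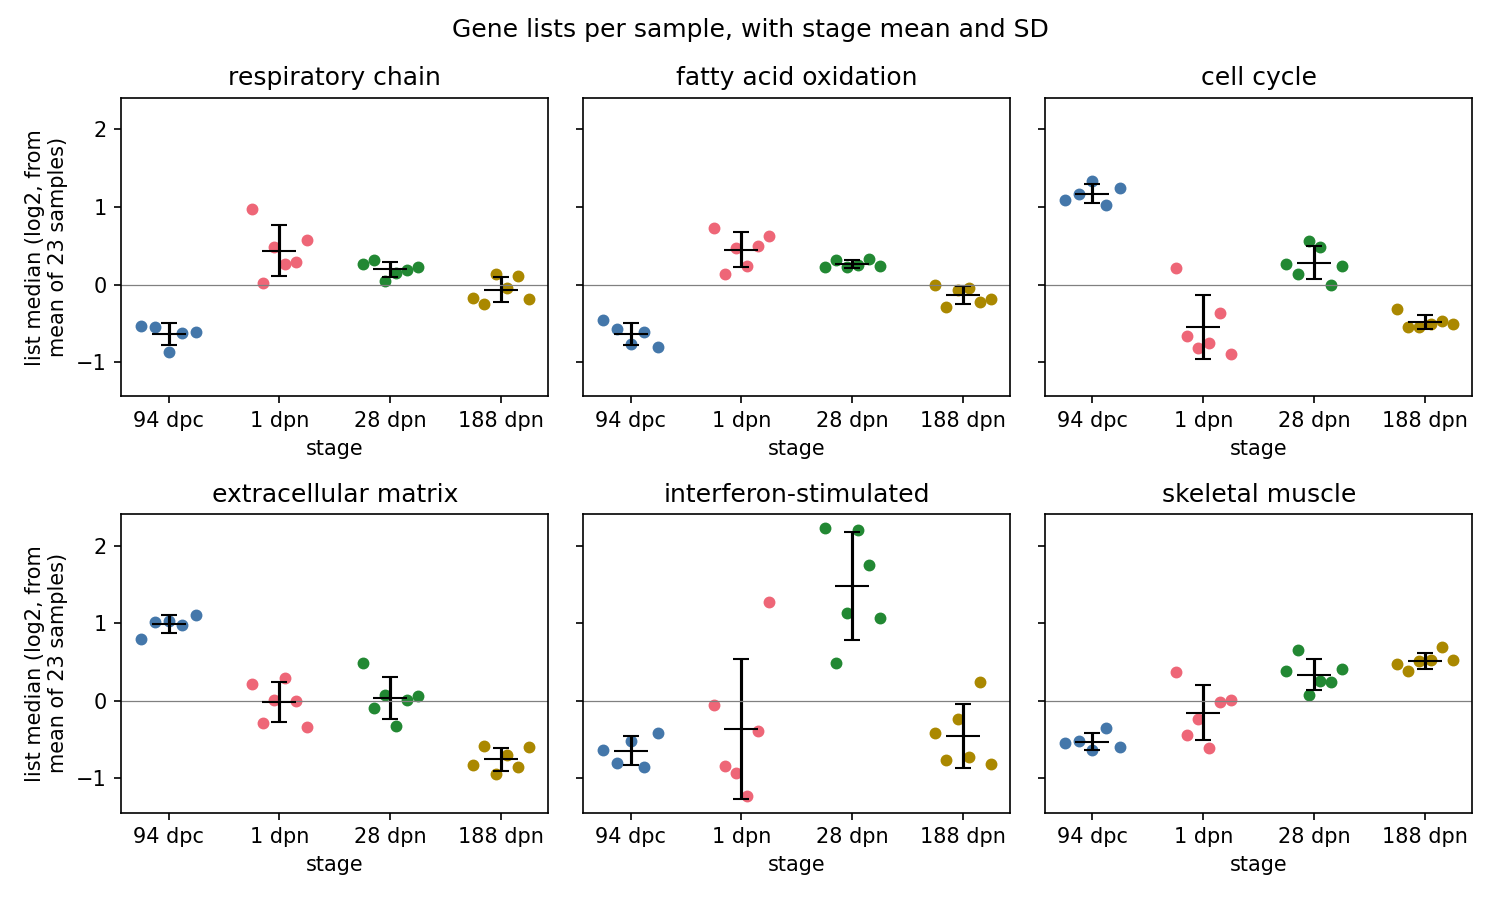
Median of 6 gene lists in each sample (log2, relative to the mean of all 23 samples), by stage, with 1 point per sample, the stage mean as a dash and the SD as a bar. The interferon-stimulated list lies at 0.49 to 2.23 in the 28 dpn samples and at 1.28 in 1 dpn replicate 6, against -0.85 to 0.24 at 94 dpc and 188 dpn. The rise of the skeletal muscle list from 94 dpc to 1 dpn turns under quantile normalization.

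The third comparison spanned the growing period from 28 to 188 dpn. As lists, interferon-stimulated, antigen presentation, macrophage, matrix and endothelial genes shifted lower at 188 dpn, with members in each that did not pass. With an estimated correlation none of them kept its call (adjusted p = 0.23, 0.31, 0.15, 0.13 and 0.076). Cardiac alpha-actin (ACTC1), the fetal actin of skeletal muscle, fell 32.1-fold (signal 987 ± 235 against 33800 ± 13600, adjusted p = 1.9e-12). The interferon-induced GTPase MX1 fell 10.7-fold (signal 182 ± 206 against 1680 ± 1400, adjusted p = 0.0012). MYF6, a myogenic regulator of mature fibres, rose 5.46-fold (signal 5780 ± 1070 against 1060 ± 309, adjusted p = 2.6e-05), and FBXO32, a muscle ubiquitin ligase, rose 5.55-fold (signal 5910 ± 2430 against 1050 ± 391, adjusted p = 0.0016).

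There were 1118 probe sets higher and 2197 lower at 188 dpn, 13.8% of 23999, and 514 and 1254 of them differed at least 2-fold. By gene, 391 were higher and 847 lower. The other large rises were those of TMEM140, UCHL1, NANOS1, GPX3, ME1, S100A1, FNTB and MRLN, at 4.09-fold to 13.1-fold. ME1 supplies NADPH for fatty acid synthesis, and MRLN encodes the small calcium pump regulator myoregulin. The other large falls were those of FNTA, IFIT3, RBP7, EVA1B, ALAS2, GBP1, IGF2 and POSTN, at 6.15-fold to 8.65-fold. ALAS2 starts heme synthesis in erythroid cells. Genes FNTA and FNTB encode the subunits of protein farnesyltransferase and changed in opposite directions, with a signal of 2930 ± 412 against 25700 ± 4780 for FNTA and 2670 ± 1200 against 572 ± 109 for FNTB, although 2 other FNTA probe sets had log2 changes of 0.29 and 0.35 that did not pass.

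Of interferon-stimulated genes, 17 of 21 fell and 4 did not pass (20 fell adjusted over the list alone), with adjusted p = 8.8e-10 for the list and adjusted p = 0.23 with an estimated correlation. The falls were largest for MX1 (-3.42 ± 0.68), ISG15 (-3.14 ± 0.79), RSAD2 (-2.99 ± 0.72) and IFIT3 (-2.97 ± 0.56). For antigen presentation, 13 of 22 fell and 9 did not pass (16 fell adjusted over the list alone), with adjusted p = 1.3e-06 for the list and adjusted p = 0.31 with an estimated correlation, led by CTSS (-2.19 ± 0.22), TAP1 (-2.05 ± 0.37), SLA-DRA (-1.69 ± 0.44) and SLA-6 (-1.65 ± 0.23). In the macrophage list, 10 of 17 fell and 7 did not pass (12 fell adjusted over the list alone), with adjusted p = 3.7e-05 for the list and adjusted p = 0.15 with an estimated correlation. Its complement C1q genes C1QA (-2.55 ± 0.36) and C1QC (-2.43 ± 0.39) fell most, followed by AIF1 (-2.25 ± 0.31) and CTSS (-2.19 ± 0.22). Among markers of matrix-forming cells, 14 of 27 fell and 13 did not pass (17 fell adjusted over the list alone), with adjusted p = 4.5e-07 for the list and adjusted p = 0.13 with an estimated correlation, with POSTN (-2.62 ± 0.34), COL4A2 (-1.69 ± 0.18), COL15A1 (-1.49 ± 0.27) and MGP (-1.32 ± 0.21) in the lead. Of endothelial markers, 9 of 15 fell and 6 did not pass (11 fell adjusted over the list alone), with adjusted p = 4.8e-05 for the list and adjusted p = 0.076 with an estimated correlation. The largest falls were those of FCN2 (-2.28 ± 0.64), LYVE1 (-1.82 ± 0.32), CDH5 (-1.48 ± 0.23) and ERG (-1.47 ± 0.33).

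In the cell cycle list, 14 of 34 fell and 20 did not pass (20 fell adjusted over the list alone), with adjusted p = 6.1e-05 for the list and adjusted p = 0.25 with an estimated correlation, led by UBE2C (-2.52 ± 0.50), NUSAP1 (-2.00 ± 0.37), CCNB1 (-1.93 ± 0.31) and TOP2A (-1.89 ± 0.27). Of respiratory chain genes, 8 of 60 fell and 52 did not pass (8 fell adjusted over the list alone), with adjusted p = 0.01 for the list and adjusted p = 0.68 with an estimated correlation. They included COX6A1 (-0.96 ± 0.20), COX7A2 (-0.76 ± 0.16), NDUFA8 (-0.75 ± 0.23) and NDUFB5 (-0.69 ± 0.20). In fatty acid oxidation, 1 of 28 rose, 10 fell and 17 did not pass (1 rose and 13 fell adjusted over the list alone), with adjusted p = 0.029 for the list and adjusted p = 0.43 with an estimated correlation. ANGPTL4 (-1.46 ± 0.33), the carnitine transporter SLC22A5 (-1.33 ± 0.29) and ECI1 (-1.23 ± 0.19) fell, while PDK4 (1.29 ± 0.41) rose. Of the fetal liver list, 3 of 7 fell and 4 did not pass (5 fell adjusted over the list alone), with adjusted p = 0.026 for the list and adjusted p = 0.23 with an estimated correlation, namely IGF2 (-2.62 ± 0.35), PEG10 (-1.66 ± 0.34) and PLAGL1 (-0.86 ± 0.29).

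Among plasma protein genes, 4 of 39 rose, 2 fell and 33 did not pass (4 rose and 3 fell adjusted over the list alone), with adjusted p = 0.0087 for the list and adjusted p = 0.63 with an estimated correlation. ALB (3.52 ± 0.94), APOC3 (3.12 ± 0.93) and VTN (1.63 ± 0.55) rose and PROS1 (-1.44 ± 0.17) fell. In urea cycle and nitrogen metabolism, 3 of 6 rose and 3 did not pass (3 rose adjusted over the list alone), with adjusted p = 0.0087 for the list and adjusted p = 0.13 with an estimated correlation, namely ASL (1.33 ± 0.24), GLUL (1.28 ± 0.28) and ASS1 (1.22 ± 0.40). Among immediate early and stress genes, 6 of 22 rose, 2 fell and 14 did not pass (9 rose and 2 fell adjusted over the list alone), with adjusted p = 0.0087 for the list and adjusted p = 0.31 with an estimated correlation. FOS (2.97 ± 0.51), HSP70.2 (1.87 ± 0.38) and JUN (1.66 ± 0.36) rose and IER3 (-1.31 ± 0.23) fell. The gluconeogenic enzyme PCK1 rose by 1.85 ± 0.60 (adjusted p = 0.039). The changes of AFP (-0.54 ± 0.56, adjusted p = 0.61), IGF1 (-0.94 ± 0.35, adjusted p = 0.074), CPS1 (0.49 ± 0.47, adjusted p = 0.57) and CYP7A1 (0.59 ± 0.26, adjusted p = 0.15) did not pass, and IGF1 passed without 188 dpn replicate 5 (adjusted p = 0.039).

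Several of these calls hung on single samples. PLAGL1 lost its call without 28 dpn replicate 1, 2, 3 or 4 or 188 dpn replicate 1, 2, 3, 4, 5 or 6 (adjusted p from 0.055 to 0.1), VTN without 28 dpn replicate 2, 3, 4, 5 or 6 or 188 dpn replicate 1, 3, 4, 5 or 6 (adjusted p from 0.053 to 0.13), PCK1 without 28 dpn replicate 2, 3, 4 or 6 or 188 dpn replicate 1, 2, 3 or 6 (adjusted p from 0.054 to 0.083) and PDK4 without 28 dpn replicate 1, 3 or 4 or 188 dpn replicate 1, 2, 3 or 6 (adjusted p from 0.059 to 0.1). Likewise, ASS1 lost it without 28 dpn replicate 2, 3, 4 or 6 or 188 dpn replicate 1 or 3 (adjusted p from 0.056 to 0.1), APOC3 without 28 dpn replicate 4 or 5 or 188 dpn replicate 6 (adjusted p from 0.062 to 0.073), NDUFA8 without 28 dpn replicate 1 or 6 or 188 dpn replicate 2 or 6 (adjusted p from 0.054 to 0.065), FCN2 without 28 dpn replicate 5 (adjusted p = 0.051) and NDUFB5 without 188 dpn replicate 2 (adjusted p = 0.054). The log2 change of ALB was 4.46 and that of APOC3 4.00 without 28 dpn replicate 1, that of APOC3 was 2.50 without 28 dpn replicate 5, and that of PCK1 was 1.12 without 188 dpn replicate 1. Fatty acid oxidation lost its call without 28 dpn replicate 5 or 188 dpn replicate 2 or 5 (adjusted p from 0.052 to 0.07). Xenobiotic metabolism passed without 28 dpn replicate 1 or 188 dpn replicate 2 or 4 (adjusted p from 0.013 to 0.049), skeletal muscle without 28 dpn replicate 1, 2 or 6 or 188 dpn replicate 2, 3 or 4 (adjusted p from 0.016 to 0.049) and pancreas and gut markers without 28 dpn replicate 1 or 188 dpn replicate 3, 4 or 6 (adjusted p from 0.024 to 0.045).

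The Dap ratio separated these stages completely, and with it as a covariate, a setting chosen after seeing the data, 530 probe sets were higher and 1044 lower. Calls that changed with the setting are given with the adjusted p in parentheses. With a pseudocount of 1, ASS1 (0.051) and VTN (0.056) did not pass, and the skeletal muscle list (0.05) did. With a pseudocount of 64, PLAGL1 (0.056) did not pass, and IGF1 (0.035), the skeletal muscle list (0.047) and the pancreas and gut list (0.049) did. Without the 3 samples of low GAPDH ratio, PCK1 (0.052) did not pass, and the skeletal muscle list (0.047) did. With the GAPDH covariate, the skeletal muscle list (0.04) passed. With the Dap covariate, MRLN (0.052), PLAGL1 (0.36), ASL (0.056), ASS1 (0.18), PDK4 (0.23), APOC3 (0.056), VTN (0.18), ERG (0.16), HSP70.2 (0.067), COX7A2 (0.065), PCK1 (0.2) and the fetal liver list (0.071) did not pass, and the pancreas and gut list (0.036) did. Fitted on the stages compared alone, ASS1 (0.12), PDK4 (0.063), APOC3 (0.054), VTN (0.093) and PCK1 (0.12) did not pass, and IGF1 (0.045) and the skeletal muscle list (0.036) did. After centring, PLAGL1 (0.093) and NDUFA8 (0.058) did not pass, and the skeletal muscle list (0.024) did. After quantile normalization, PLAGL1 (0.08) and PDK4 (0.056) did not pass. Without the dimmer probe sets, the plasma protein list (0.22) did not pass, and IGF1 (0.035) did. Under array weights, IGF1 (0.017) and the skeletal muscle list (0.03) passed. With the mean of all probe sets per gene, the fatty acid oxidation list (0.073) did not pass, and the xenobiotic metabolism list (0.02) did. By camera on ranks, the skeletal muscle list (0.025) and the pancreas and gut list (0.037) passed. Under the trend and robust options, VTN (0.061) and PCK1 (0.054) did not pass, and the skeletal muscle list (0.037) did. Of called probe sets, 33.7% were higher as deposited, 42.5% after quantile normalization and 46.6% after centring. Of 42 other probe sets of called genes, 17 passed in the same direction. Log2 changes of the same sign that did not pass were those of NANOS1 (0.27), GBP1 (-0.87), IGF2 (-0.68, -0.73 and -0.10), POSTN (-0.29), PEG10 (-0.93), PLAGL1 (-0.78), UBE2C (-0.55), NUSAP1 (-0.32), GLUL (0.79), ANGPTL4 (-0.84), CTSS (-0.71), TAP1 (-0.05), LYVE1 (-0.70) and CDH5 (-0.31). The opposite sign was found for FNTA (0.29 and 0.35), IGF2 (0.06, 0.12 and 0.09), PEG10 (0.44), TAP1 (0.26), SLA-6 (0.25) and LYVE1 (0.01).

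Over the whole span from 94 dpc to 188 dpn, the fetal, matrix, endothelial and cell cycle lists shifted lower, and those of skeletal muscle, glycolysis and fatty acid oxidation shifted higher. With an estimated correlation none of them kept its call (adjusted p = 0.06, 0.06, 0.06, 0.11, 0.2, 0.38 and 0.25). Glycolysis also lost it under both other scalings, with 5 of its 16 genes lower, and 16 of 28 fatty acid oxidation genes did not pass. PEG10 fell 140-fold (signal 126 ± 41.2 against 19000 ± 3250, adjusted p = 1.3e-12), while its other 2 probe sets had log2 changes of -1.01 (adjusted p = 0.1) and -0.26 (adjusted p = 0.59). ACTC1 fell 38.1-fold (signal 987 ± 235 against 37500 ± 4400, adjusted p = 4.8e-13). Periostin (POSTN) fell 68-fold (signal 162 ± 65.8 against 11900 ± 3660, adjusted p = 1.1e-11). PDK4 rose 34.7-fold (signal 16500 ± 8300 against 427 ± 166, adjusted p = 2.1e-09), and the mitochondrial carrier UCP3 rose 32.5-fold (signal 2330 ± 1170 against 57 ± 37.4, adjusted p = 4.7e-10).

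Here 3202 probe sets were higher and 5612 lower at 188 dpn, 36.7% of 23999, and 1992 and 4076 of them differed at least 2-fold. By gene, 1316 were higher and 1855 lower. The other large rises were those of CST6, LOC100153598, MSS51, CYP3A29, C4BPA, TRNP1, DEFB1 and BPGM, at 20.6-fold to 40.5-fold. CYP3A29 is a porcine cytochrome P450, DEFB1 a beta-defensin and BPGM is the bisphosphoglycerate mutase of red cells. The other large falls were those of LOC396711, IGSF1, TNNT2, MEG3, PTN, ASPN and C3H2orf40, at 25.9-fold to 158-fold. MEG3 is a maternally expressed noncoding RNA, PTN a growth factor related to midkine and ASPN a matrix proteoglycan.

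Among markers of matrix-forming cells, 1 of 27 rose, 25 fell and 1 did not pass (1 rose and 25 fell adjusted over the list alone), with adjusted p = 1.1e-08 for the list and adjusted p = 0.06 with an estimated correlation. The falls were led by POSTN (-6.09 ± 0.36), COL5A1 (-2.89 ± 0.22), BGN (-2.67 ± 0.30) and COL4A2 (-2.62 ± 0.19). In the cell cycle list, 1 of 34 rose, 28 fell and 5 did not pass (1 rose and 31 fell adjusted over the list alone), with adjusted p = 3.2e-07 for the list and adjusted p = 0.11 with an estimated correlation, with UBE2C (-3.81 ± 0.52), NUSAP1 (-3.20 ± 0.39), CCNB2 (-3.14 ± 0.50) and CCNB1 (-2.91 ± 0.32) falling most. Of endothelial markers, 12 of 15 fell and 3 did not pass (12 fell adjusted over the list alone), with adjusted p = 0.00035 for the list and adjusted p = 0.06 with an estimated correlation. These included FCN2 (-2.91 ± 0.67), CDH5 (-2.33 ± 0.24), ERG (-2.27 ± 0.35) and LYVE1 (-2.08 ± 0.34). All measured members of the fetal liver list fell: 7 of 7 fell (7 fell adjusted over the list alone), with adjusted p = 0.00035 for the list and adjusted p = 0.06 with an estimated correlation. The largest falls were those of PEG10 (-7.13 ± 0.35), IGF2 (-4.59 ± 0.37), PLAGL1 (-4.00 ± 0.30) and AFP (-3.66 ± 0.58). For the skeletal muscle list, 20 of 26 rose, 2 fell and 4 did not pass (21 rose and 2 fell adjusted over the list alone), with adjusted p = 3.4e-08 for the list and adjusted p = 0.2 with an estimated correlation. MYH2 (3.88 ± 0.31), ATP2A1 (3.87 ± 0.17) and the glycogen phosphorylase PYGM (2.85 ± 0.26) rose, and MYF5 (-3.29 ± 0.32) fell.

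For glycolysis, 10 of 16 rose, 5 fell and 1 did not pass (10 rose and 6 fell adjusted over the list alone), with adjusted p = 0.032 for the list and adjusted p = 0.38 with an estimated correlation. The muscle phosphofructokinase PFKM (3.66 ± 0.31) led, followed by GPI (3.41 ± 0.24), LDHA (2.83 ± 0.44) and PGK1 (2.60 ± 0.25). In gluconeogenesis and glycogen metabolism, 8 of 14 rose, 1 fell and 5 did not pass (8 rose and 1 fell adjusted over the list alone), with adjusted p = 0.0018 for the list and adjusted p = 0.088 with an estimated correlation, the largest rises being those of SLC37A4 (4.12 ± 0.22), FBP2 (3.81 ± 0.60), PGM1 (3.12 ± 0.28) and GYG1 (2.65 ± 0.24). FBP2 is the fructose bisphosphatase of muscle. Of fatty acid oxidation genes, 12 of 28 rose and 16 did not pass (12 rose adjusted over the list alone), with adjusted p = 0.0021 for the list and adjusted p = 0.25 with an estimated correlation. PDK4 was followed by ACADS (1.83 ± 0.25), ACADM (1.52 ± 0.25) and ANGPTL4 (1.46 ± 0.34). Among respiratory chain genes, 31 of 60 rose, 2 fell and 27 did not pass (33 rose and 2 fell adjusted over the list alone), with adjusted p = 4.6e-07 for the list and adjusted p = 0.38 with an estimated correlation. COX6A1, the ubiquitous form of its subunit, fell (-1.89 ± 0.21), while ATP5J (1.75 ± 0.14), SDHC (1.73 ± 0.26) and NDUFC1 (1.66 ± 0.19) rose. In amino acid breakdown, 11 of 28 rose and 17 did not pass (12 rose adjusted over the list alone), with adjusted p = 0.0038 for the list and adjusted p = 0.2 with an estimated correlation, led by BCKDHB (2.34 ± 0.29), DAO (1.69 ± 0.41), BCAT2 (1.60 ± 0.36) and GOT2 (1.55 ± 0.16). For the antioxidant and metal-binding list, 14 of 26 rose, 4 fell and 8 did not pass (14 rose and 5 fell adjusted over the list alone), with adjusted p = 0.008 for the list and adjusted p = 0.29 with an estimated correlation. GPX3 (3.19 ± 0.39), SOD2 (2.92 ± 0.23) and GCLM (2.24 ± 0.34) rose and the metallothionein MT3 (-2.89 ± 0.51) fell.

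ALB rose by 3.30 ± 0.99 on the log2 scale (adjusted p = 0.01) and PCK1 by 1.93 ± 0.63 (adjusted p = 0.017), the latter by 1.21 without 188 dpn replicate 1 (adjusted p = 0.02). IGF1 changed by -1.17 ± 0.36 (adjusted p = 0.013). The changes of CPS1 (0.04 ± 0.49, adjusted p = 0.96) and CYP7A1 (0.54 ± 0.27, adjusted p = 0.13) did not pass, although CYP7A1, the rate-limiting enzyme of bile acid synthesis, passed without 188 dpn replicate 2 (adjusted p = 0.047).

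The share of called probe sets that were higher at 188 dpn was 36.3% as deposited, 48.8% after quantile normalization and 56.9% after centring. The median log2 change of all probe sets was -0.077, 0.077 and 0.217. The following calls changed, with the adjusted p in parentheses. Fitted on the stages compared alone, PCK1 (0.068) did not pass. After centring, IGF1 (0.058) and the glycolysis list (0.076) did not pass, and CYP7A1 (0.021) did. After quantile normalization, IGF1 (0.086), the glycolysis list (0.21), the antioxidant list (0.1) and the respiratory chain list (0.44) did not pass, and the ribosomal protein list (5.3e-09) did. With the mean of all probe sets per gene, the xenobiotic metabolism list (0.024) passed. By camera on ranks, the glycolysis list (0.12) did not pass, and the bile acid list (0.05) did. Of 45 other probe sets of called genes, 25 passed in the same direction. Log2 changes of the same sign that did not pass were those of DEFB1 (0.31), PEG10 (-1.01 and -0.26), IGF2 (-0.49, -1.05, -0.60 and -0.32), PLAGL1 (-1.11), UBE2C (-0.22), LYVE1 (-0.33), GCLM (0.03), ATP5J (0.24) and IGF1 (-0.50). The opposite sign was found for LOC100153598 (-0.72), PTN (0.15), IGF2 (0.78 and 0.21), COL5A1 (0.11 and 0.85) and IGF1 (0.49).

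Transcripts that peaked or dipped around birth were those called in opposite directions in both comparisons with 1 dpn. Of these, 640 probe sets were highest at 1 dpn and 1153 lowest. ATP5I, a subunit of ATP synthase, was among the former, with mean signals of 2970 ± 2290, 15500 ± 3080 and 2680 ± 1750 at 94 dpc, 1 dpn and 28 dpn. Its other probe set showed no such peak, with log2 changes of 0.09 (adjusted p = 0.87) and 0.46 (adjusted p = 0.33). In the same order, the motor protein gene MYO5B had 143 ± 103, 1190 ± 375 and 118 ± 34.7, and ANKRD1 had 726 ± 327, 8160 ± 2950 and 1810 ± 863. Among the lowest, MDK had 3330 ± 502, 74.5 ± 90.4 and 936 ± 322. CCNB1 had 447 ± 83.1, 33.2 ± 28.2 and 219 ± 40, and TNNT2 had 3230 ± 711, 53 ± 64.1 and 297 ± 219. Both comparisons share the 1 dpn samples, and independent lists of the same lengths would share 136 and 435 probe sets. In 20 simulations of unchanged groups the largest overlap was 0 and 0, which leaves out the effects and so does not measure what the shared samples add to them. With 3 of the 1 dpn samples used in each comparison, the medians over 20 splits were 406 (344 to 452) and 730 (539 to 880). Part of the excess over independent lists may come from the shared samples. After centring, 1013 were highest and 679 lowest. Without the 3 samples of low GAPDH ratio at 1 dpn, 580 were highest and 1011 lowest, and with that ratio as a covariate 549 and 906.

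Over all 4 stages, 11185 probe sets differed between some of them by limma's F test. Of 34 lists tested, 9, 9, 12 and 11 shifted in the comparisons above, in the order given. With an estimated correlation, fatty acid oxidation between 94 dpc and 1 dpn was the only list that kept its call.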

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

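Tests in this part were chosen only after the result was seen, except those of wrong sample records and of liver RNA carried over. Among named genes, 420 groups of samples were searched for a sample far from the others of its stage by Dixon's test, and 33 had one, where chance gives about 21. Among called lists it was 3 of 58, where chance gives about 3.

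At 94 dpc, the sample that stood apart in signal was replicate 3 for ALB (1160, others 163 to 272), replicate 1 for C3H2orf40 (736, others 3190 to 4250), replicate 4 for CKS2 (1230, others 1590 to 1720), replicate 5 for CST6 (7.18, others 58.9 to 85.1) and replicate 2 for LOC100153598 (2640, others 567 to 828) and PCK2 (38.3, others 67.8 to 77.3). The respiratory chain list median (log2, from the mean of all samples) was -0.87 in 94 dpc replicate 3, against -0.63 to -0.53 in the others.

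At 1 dpn, the sample that stood apart in signal was replicate 1 for HSPB7 (3070, others 6860 to 10100), replicate 2 for PPP1R3B (1130, others 3130 to 5540) and SPP1 (673, others 203 to 294) and replicate 4 for XIRP2 (5770, others 8850 to 10800).

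At 28 dpn, the sample that stood apart in signal was replicate 1 for ALB (6400, others 34.5 to 174), POSTN (2340, others 704 to 1030) and VTN (1100, others 86.1 to 136), replicate 3 for ASS1 (192, others 336 to 460) and COL15A1 (7780, others 5630 to 6330), replicate 2 for EVA1B (208, others 404 to 588), replicate 5 for HIBCH (238, others 350 to 402) and replicate 6 for MYF6 (1670, others 860 to 1050). The plasma protein list median (log2, from the mean of all samples) was 1.48 in 28 dpn replicate 1, against -1.01 to -0.69 in the others.

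At 188 dpn, the sample that stood apart in signal was replicate 2 for ALAS2 (7.7, others 104 to 210), CDH5 (398, others 718 to 1010), IFIT3 (5.06, others 124 to 402), PEG10 (47.3, others 118 to 163) and SLA-6 (288, others 368 to 389), replicate 4 for ASL (294, others 529 to 661), CCNB1 (14.3, others 43.2 to 57.3), LOC100153598 (48200, others 21600 to 27600) and LYVE1 (3.99, others 68.5 to 109), replicate 1 for COX6A1 (3560, others 1720 to 1960), GPX3 (5370, others 985 to 1440), PCK1 (10100, others 217 to 864) and UCHL1 (506, others 1170 to 1490) and replicate 5 for ME1 (2080, others 2430 to 2590) and TRNP1 (532, others 715 to 832). The cell cycle list median (log2, from the mean of all samples) was -0.31 in 188 dpn replicate 1, against -0.55 to -0.47 in the others.

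Muscle transcripts lay above liver transcripts in the samples labelled liver, by percentiles that set different probe sets against each other. Pieces of liver with adhering muscle would keep plasma protein genes at a median percentile above 90 in some sample. The highest, in 28 dpn replicate 1, was 80.6 (bootstrap SE over the genes 4.8). It lies under that bound by less than 2 SE, so such pieces stay open for that sample. In 28 dpn replicates 2 to 6 the percentile was 23.5 to 40.3, with the muscle list at 99.7. Those values argue against liver with adhering muscle in these replicates, although the bound was not set for each sample. Samples of the other stages lay at 28.7 to 75.3, with the muscle list at 99 to 99.8. As a set these values also lie under 90 and argue against liver with adhering muscle there. The SE was computed only for the highest value of all, so these samples were not judged singly. A wrong tissue entry was to place the xenobiotic metabolism genes at a highest median percentile under 60, and liver above 75. The highest value, 71.9 in 188 dpn replicate 6, lay between and decides nothing by that rule. Above 60 lay only 1 dpn replicate 2, 28 dpn replicate 1 and 188 dpn replicates 1, 4 and 6. All other samples lay under 60, those of 94 dpc at 32.9 to 43, and no sample reached 75. The bounds were set for the highest value and not for each sample. Whether the records name the wrong tissue or the signals belong to other samples stays open as well, and no biological explanation was tested, since the labels give 1 tissue.

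Plasma protein transcripts differed together between samples of one stage, with a median pairwise correlation of 0.43 over the within-stage deviations of 39 genes, none of which is in another list. Loss of signal at the 5' end would leave the list median within 1 (log2) among the 20 samples of normal GAPDH ratio, and it differed by 2.95, which argues against it as the whole cause. At 1 dpn it stays open, since the 3 samples of low ratio were the 3 highest (0.52 to 0.80, others -1.23 to 0.05) and the exact two-sided permutation p of 0.1 is the smallest that 3 against 3 allow. Liver RNA carried over into the samples would bring 78 other hepatocyte genes along, and their median correlation with the plasma protein median was 0.08 (bootstrap SE 0.045), above 89.3% of 1000 random lists. The bound for excluding it was 0.1, and because the value lay under it by less than its SE, it was read as undecided, a reading chosen after the value was seen, so that carried-over liver RNA stays open, as does an untested difference between the animals.

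A low 5' to 3' ratio marked 1 dpn replicates 2, 4 and 5. RNA degraded in the tissue would leave the added Phe transcript intact, and the highest Phe ratio of the 3 was 0.178 against at least 0.591 in the other 20, which argues against degradation as the whole cause. A shortfall in labelling may account for it, since the Lys ratio was low as well (at most 0.122 against at least 0.352), although the actin ratio (0.817 to 1.01) overlapped that of the others (0.82 to 1.61). Whether the 3 samples make the counts with 1 dpn stays open: without them the largest change was 1.37 times, and 46.3% to 74.4% of the called probe sets were still called, but the GAPDH covariate took those lower at 28 dpn from 1686 to 1112, or 1.52 times. No biological explanation was tested, since the design gives none.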

How the results depend on the processing

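The settings without the 3 samples of low GAPDH ratio and with the GAPDH or Dap ratio as a covariate were chosen only after the results were seen. No paired analysis was possible because the replicate numbers follow accession order and the labels give neither dam nor pair. Counts of called probe sets or lists that moved by more than 1.5 times were the following, and the cause was not tested. Centring each array on its median gave 3611 higher and 2473 lower between 94 dpc and 1 dpn, 5281 higher between 94 dpc and 188 dpn, 1013 highest at 1 dpn and 679 lowest. Fitting the 1 and 28 dpn samples alone gave 1487 higher and 966 lower. Such a fit has fewer samples to estimate the spread, but that alone does not account for the drop. Fitting 28 and 188 dpn alone gave more calls than the main fit, 1627 higher and 2496 lower against 1118 and 2197. The GAPDH covariate gave 1112 lower between 1 and 28 dpn, and the Dap covariate 530 higher and 1044 lower between 28 and 188 dpn. With the estimated correlation, 1, 0, 0 and 0 lists shifted, against 9, 9, 12 and 11.

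Leaving out 1 sample at a time moved no count by more than 1.5 times. The ranges of probe sets higher and lower were 1633 to 2037 and 3506 to 4285 for 1 dpn against 94 dpc, 2032 to 2739 and 1344 to 1980 for 28 dpn against 1 dpn, 913 to 1018 and 1876 to 2159 for 188 dpn against 28 dpn, 2819 to 3046 and 5114 to 5482 for 188 dpn against 94 dpc. Those called between any stages numbered 10386 to 11476, highest at 1 dpn 530 to 757 and lowest 931 to 1391. Lists shifted were 7 to 10, 9 to 12, 11 to 15, 11 to 11 in the same order. Of 232 called pairs of a named gene and a comparison, 217 kept their call in every such fit and 15 lost it in 1 or more.

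Among called genes, the directions that turned were those of other probe sets carrying a gene's symbol, and the cause was not tested. Their log2 changes were, between 94 dpc and 1 dpn, LOC100153598 (-0.16), VCAN (0.40 and 0.05), UBE2C (0.26), COL5A2 (0.45) and IGF1 (0.34), between 1 and 28 dpn, PEG10 (1.89), ATP5I (0.46), IGF2 (1.13 and 1.45), CTSS (-0.16), RPS25 (0.45) and IGF1 (-0.29), between 28 and 188 dpn, FNTA (0.29 and 0.35), IGF2 (0.06, 0.12 and 0.09), PEG10 (0.44), TAP1 (0.26), SLA-6 (0.25) and LYVE1 (0.01), and between 94 dpc and 188 dpn, LOC100153598 (-0.72), PTN (0.15), IGF2 (0.78 and 0.21), COL5A1 (0.11 and 0.85) and IGF1 (0.49). Among the lists, quantile normalization turned skeletal muscle (adjusted p = 0.94) and ribosomal proteins (adjusted p = 0.00066) between 94 dpc and 1 dpn. Of changes not called, ALB between 94 dpc and 1 dpn turned without the samples of low GAPDH ratio (-0.14) and with the GAPDH covariate (-0.18), AFP between 28 and 188 dpn with the Dap covariate (0.21), CYP7A1 between 94 dpc and 1 dpn without 1 sample (-0.02) and CPS1 between 94 dpc and 188 dpn with a pseudocount of 1 (-0.02) and without single samples (-0.24 to -0.05).

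Of the 248 named pairs, calls ended in 5 under quantile normalization, 4 under centring, 3 under a pseudocount of 1, 1 under a pseudocount of 64, 11 under fitting only the stages compared, 1 under array weights, 2 under the trend and robust options, 11 under leaving out the samples of low GAPDH ratio, 10 under the GAPDH covariate and 15 under the Dap covariate. Of the 232 called pairs, folds moved by more than 1.5 times in 5 under quantile normalization, 21 under a pseudocount of 1, 43 under a pseudocount of 64, 20 under leaving out the samples of low GAPDH ratio, 22 under the GAPDH covariate and 14 under the Dap covariate. Signals under 100, where the added 16 weighs most, made up 39.1% to 45.7% of the probe sets of an array. Without detection calls, a low signal cannot be told from background.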

Other observations

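The counts over other splits of the samples were chosen only after the results were seen. Gene levels outside the rule for named genes were picked after their values were seen and are given as values. Interferon-stimulated genes stood high in 6 of 6 samples at 28 dpn, with list medians of 0.49 to 2.23 above the mean of all samples, against -0.85 to 0.24 at 94 dpc and 188 dpn. At 1 dpn, replicate 6 had 1.28 and the others -1.23 to -0.06. The ubiquitin-like modifier ISG15 had mean signals of 250 ± 58, 3070 ± 6090, 5790 ± 4140 and 685 ± 721 at 94 dpc, 1, 28 and 188 dpn, with 15400 in 1 dpn replicate 6. Among plasma protein genes, in the same order of stages, APOA1 had 8760 ± 1300, 3470 ± 463, 2260 ± 946 and 1380 ± 494, and AHSG (fetuin) 6350 ± 4540, 2280 ± 1940, 550 ± 955 and 572 ± 335, while ALB had 385 ± 435, 1230 ± 1080, 1170 ± 2560 and 3640 ± 2880 and HP (haptoglobin) 199 ± 85.5, 2140 ± 1630, 1430 ± 3240 and 1850 ± 1740.

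Transcripts of the exocrine pancreas differed between samples of one stage. CPB1, a procarboxypeptidase, reached 1550 at 188 dpn and at most 168 at the other stages, CLPS reached 1170 at 188 dpn and 1050 at 1 dpn, PRSS2 1120 and 537, and CPA1 1240 and 2900. The samples above 400 for CPB1, CLPS and PRSS2 at 188 dpn numbered 2, replicates 1 and 2 for each gene. Those for CLPS and PRSS2 at 1 dpn numbered 1, replicate 5 for both. For CPA1 they numbered 2 each at 94 dpc, 1 dpn and 188 dpn, and its 94 dpc signals lay between 202 and 513. Its 2 samples were again replicates 1 and 2 at 188 dpn, and replicates 4 and 5 at 1 dpn. The cause of this joint pattern was not tested. EIF1AY, a gene of the Y chromosome, lay above 400 in 2 of 5 samples at 94 dpc, 4 of 6 at 1 dpn and 3 of 6 at 28 and at 188 dpn. Sex was not a term of the model, and its effect on the comparisons was not tested.

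The 16 lists that camera called in none of the comparisons had the following lowest adjusted p: erythroid markers (0.14), methionine and one-carbon metabolism (0.66), lipogenesis (0.2), cholesterol synthesis (0.15), bile acid genes (0.11), xenobiotic metabolism (0.069), acute phase and complement (0.11), the growth hormone axis (0.31), lymphocyte markers (0.2), granulocyte markers (0.063), platelet markers (0.62), cholangiocyte markers (0.23), pancreas and gut markers (0.068), hepatocyte transcription factors (0.49), circadian genes (0.2) and endoplasmic reticulum stress (0.4).

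Other splits of the samples were compared with the real ones, 100 each with the real one included, as a test of chance. For probe sets higher at 1 dpn than at 94 dpc, 3 of 100 splits gave as many (real 1939, highest other 2832), and for those lower 1 (4284, 1361). Between 1 and 28 dpn it was 1 for higher (2435, 155) and 1 for lower (1686, 155), between 28 and 188 dpn 1 (1118, 46) and 1 (2197, 46), and between 94 dpc and 188 dpn 2 (3202, 4482) and 1 (5612, 2340). Probe sets that differed between any stages gave 1 (11185, 5), those highest at 1 dpn 2 (640, 995) and those lowest 1 (1153, 445). Chance is excluded for these counts at a share under 0.05 only if the animals are taken as independent, which offspring of 3 gilts per stage are not. The splits that exceeded the real number of probe sets higher than at 94 dpc had moved 5 of the 6 later samples into the other group, so they are near mirror images of the real split, with its larger number of lower probe sets counted as higher. They reflect that the samples group by stage. Such splits cannot tell age from array processing that differed between stages, since control measures separated stages as well. The number of lists shifted was reached by 35 of 100 splits between 94 dpc and 1 dpn (9, highest other 14), by 12 between 1 and 28 dpn (9, 11), by 11 between 28 and 188 dpn (12, 15) and by 27 between 94 dpc and 188 dpn (11, 14). Chance is not excluded for these numbers of lists.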
